A study of Homo sapiens with 6 samples.

How the data were processed

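The series holds 6 Affymetrix expression arrays of total RNA from primary HMVEC-LBI cells, 3 from cells given an siRNA against PBEF and 3 from cells given a scrambled siRNA. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited table holds log2 expression values for 54675 probe sets on each array. The authors made these values with RMA, per the submitters' processing notes, and its version and options are not given in the sources used here. RMA usually subtracts background, normalises between arrays and summarises probes, but the deposited columns do not share one distribution, so that which of its steps ran on all 6 arrays together stays unknown. No other step was undone or repeated for the main results. The sources used here give no batch, scan or hybridisation labels. No scanner files were used here. Both the group and the replicate number of each array were taken from the sample titles. The 6 columns hold no duplicate arrays.

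Probe sets were named through the platform annotation given for the value table. Of the 54675 probe sets, 41097 had exactly 1 gene symbol, 1801 had several and 11777 were not listed and so are unnamed here. The 62 control probe sets of the array represented no gene. For 41043 of the 41097 the gene ID was found in the reference gene table, and 0 symbols needed an update. Each of 19775 genes was represented by the probe set with the highest mean over the 6 arrays among those that name that gene alone. Gene names were taken from no probe set with several symbols. Genome coordinates are not given, since the files name no genome build.

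Levels were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without an intensity trend, without robust estimation, with equal array weights and without covariates, on all 6 arrays. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05. Every probe set of NAMPT was reported, with p-values adjusted over all probe sets. Each fold is 2 raised to the size of the log2 change, so it describes RMA signal and not molecules. In all, 26 gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists. The result of 1 of these lists is not reported here. The same test with an estimated correlation, and fry, were run beside it. Each list was also compared with 10000 random lists of equal size matched on mean expression.

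The groups, the tests, the 26 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named NAMPT, then the 10 genes with the largest rise and the 10 with the largest fall among called genes with groups that did not overlap and a mean log2 level of at least 5. It then named up to 4 called members with the smallest adjusted p, in the list's direction, from each list called by camera, and up to 2 from each other list, as values only where nothing passed. XIST and Y-linked genes were left out of the naming.

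The steps were tested on simulated data for 19775 genes, each with its own residual spread on the real arrays. For the comparison of PBEF siRNA with scrambled siRNA, limma recovered 22 of 67 genes changed by 0.5 on the log2 scale (32.8%), 61 of 67 changed by 1 (91.0%) and 65 of 66 changed by 2 (98.5%). Of 152 genes called, 4 had not been changed, and with no gene changed 0 were called. Camera called the 1 shifted list and 0 of 25 unshifted lists. The simulated noise was independent between genes and held no difference in signal range between arrays. In the real data the estimated correlation within a list reached 0.90, so these counts do not show how often camera miscalls correlated lists. In place of depth, the number of arrays limits the precision.

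Alternatives were the replicate number as a block, a filter on dim genes, quantile normalisation or median centring of the arrays, other ways to represent a gene, trend, robust and array-weight options of limma, and leaving out each array. Cyclic loess normalisation, quantile normalisation with an estimated correlation, and quantile normalisation with scrambled siRNA replicate 1 left out were chosen after seeing the data. A further 8 gene lists, used only in the closing observations, were also chosen after seeing the data. Probe sets without a single gene symbol entered no comparison of genes.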

Results

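Gene expression was measured on 6 oligonucleotide arrays of total RNA from primary HMVEC-LBI cells, a culture of human microvascular endothelial cells, the cells that line small blood vessels. Of these, 3 arrays came from cells given a small interfering RNA (siRNA) against PBEF and 3 from cells given a scrambled siRNA, a control sequence meant to match no transcript. PBEF is the older name of NAMPT, the enzyme that makes nicotinamide mononucleotide from nicotinamide and so limits the recycling of NAD. The comparison asks which transcripts differed in level once NAMPT was targeted. The labels call the samples of a group biological replicates without describing donors or cultures, so the p-values measure the spread between these samples. With 3 arrays per group, the number of arrays limits the precision.

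NAMPT mRNA, the target, fell on all 3 PBEF siRNA arrays by 3 of its 4 probe sets. Probe set 217738_at read a log2 signal of 6.99 ± 0.37 (SD, n = 3) with PBEF siRNA against 10.08 ± 0.22 with scrambled siRNA, which is 8.53-fold lower or 11.7% of the control level. Probe set 217739_s_at read 7.62 ± 0.38 against 10.67 ± 0.13, or 12.1% of the control level, and 1555167_s_at read 6.49 ± 0.27 against 8.60 ± 0.34, or 23.1%. The log2 changes were -3.09 ± 0.18 (SE), -3.05 ± 0.17 and -2.12 ± 0.18, with limma adjusted p-values over all probe sets of 1.33e-05, 1.28e-05 and 0.000122. The probe set 243296_at did not follow: it read 9.71 ± 0.30 against 9.37 ± 0.16, a log2 change of 0.34 ± 0.15 with an adjusted p of 0.167. The rule fixed in advance, the highest mean over the 6 arrays, takes this last probe set as the gene's value, although the other 3 show the knockdown.

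**Figure D1:**
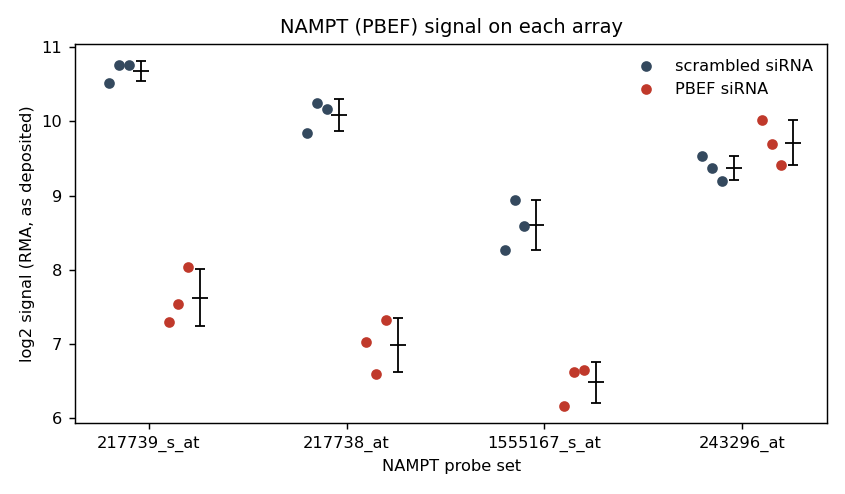
Log2 signal (vertical axis, RMA values as deposited) of the 4 NAMPT probe sets (horizontal axis) on each array, with points for single arrays and bars for the mean ± SD of 3 arrays per group. The PBEF siRNA arrays lie below the scrambled siRNA arrays for 3 probe sets, and slightly above on average for 243296_at.

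By the brightest probe set of each gene, the largest rise was that of EPS15, an adaptor protein of endocytosis, at 9.73-fold (log2 change 3.28 ± 0.13, SE). CXCL10, a chemokine that interferons induce, was 7.88-fold higher (2.98 ± 0.15) and the glycolytic enzyme PGK1 was 7.74-fold higher (2.95 ± 0.11), or 10.5-fold by its dimmer probe set with the largest change. GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose 5.96-fold, and RGCC, a regulator of cell cycle kinases, rose 5.60-fold. PKIA, an inhibitor of protein kinase A, rose 5.13-fold. The related RNA-binding proteins PCBP1 and PCBP2 rose 4.95-fold and 4.90-fold, the mannosyltransferase ALG2 rose 4.63-fold, and the cholesterol ester hydrolase NCEH1 rose 4.16-fold. In the other direction, and apart from NAMPT itself, CCL20, a chemokine for cells with the receptor CCR6, had the largest change by this measure, a log2 change of -2.38 ± 0.13 and a level 5.20-fold lower. HAPLN1, which links hyaluronan to proteoglycans, was 3.21-fold lower (log2 change -1.68 ± 0.12), and the neuroendocrine chaperone SCG5 was 3.12-fold lower. TNFRSF11B, the decoy receptor osteoprotegerin, was 2.77-fold lower. The extracellular matrix gene FREM3 and the G protein regulator RGS7 were both 2.71-fold lower, DSEL was 2.48-fold lower, LINC01279 2.43-fold, MYOZ2 2.35-fold and PCDH10 2.21-fold. All 20 of these genes had limma adjusted p-values of 0.000726 or less. In each the 3 values of one group lay outside those of the other, which the rule for naming required. EPS15, PGK1, GCH1, RGCC, PCBP2, RGS7 and MYOZ2 were read by probe sets whose suffix marks possible cross-hybridisation, and GCH1 has no other. EPS15 and PGK1 also rose by probe sets without that suffix. For RGCC, PCBP2, RGS7 and MYOZ2 the brightest probe set without it gave log2 changes of -0.16, -0.67, 0.0053 and -0.22. This ended the calls of RGCC, RGS7 and MYOZ2 and turned that of PCBP2. Over all probe sets, however, the PCBP2 value of -0.67 was not called (limma adjusted p 0.0803). Another PCBP2 probe set without the suffix was called higher (1.11, limma adjusted p 0.00114). The brightest probe sets without the suffix for RGCC, RGS7 and MYOZ2 were dim, at 5.05, 5.50 and 4.72 with scrambled siRNA, and so weigh little. A further suffixed probe set was called with the change for RGCC (1.22) and MYOZ2 (-1.96), and RGS7 has none. Of the 10 genes with the largest rise, 6 have another probe set, and for 5 of these another was called higher. ALG2 has 1 further probe set, which read -0.087 and was not called.

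Of 19775 genes, 3707 were called changed by limma after Benjamini-Hochberg adjustment, 2723 higher and 984 lower with PBEF siRNA, so that 73.5% of the calls were higher. At 2-fold or more, 178 genes were higher and 21 lower. In 3613 of the called genes the groups did not overlap, and over all genes 37.3% had groups that did not overlap, where chance gives 10%. The direction followed signal level. Among the 3971 genes with a mean log2 signal of 10 or more, 1163 were higher and 66 lower, with a median change of 0.28 over all of them. Among the 3127 genes under 6, 20 were higher and 133 lower, with a median change of -0.076. The deposited values also spread more on the PBEF siRNA arrays, with a standard deviation over probe sets of 2.13 ± 0.05 (SD, n = 3) against 2.02 ± 0.05. The 18 probe sets of hybridisation controls, which read RNA added during the assay and not RNA from the cells, averaged 10.27 ± 0.17 against 9.97 ± 0.11. The scrambled siRNA replicate 1 array had the widest gap between the 3' and 5' ACTB control probe sets, 0.86 on the log2 scale against 0.15 to 0.35 on the other arrays. When the arrays were brought to the same distribution by quantile normalisation, 3073 genes were called, 1476 higher and 1597 lower, so that 48.0% were higher. On both scales 2213 genes were called, 1384 of them higher on both, 829 lower on both and 0 in opposite directions. The count varied when single arrays were left out. It was 1493, 1250 and 6188 without PBEF siRNA replicate 1, 2 or 3. Without scrambled siRNA replicate 1, 2 or 3 it was 1942, 2092 and 3891. These fits had fewer arrays, which can by itself lower a count. After quantile normalisation the count was 1949 without scrambled siRNA replicate 1, a check chosen after seeing the data.

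**Figure D2:**
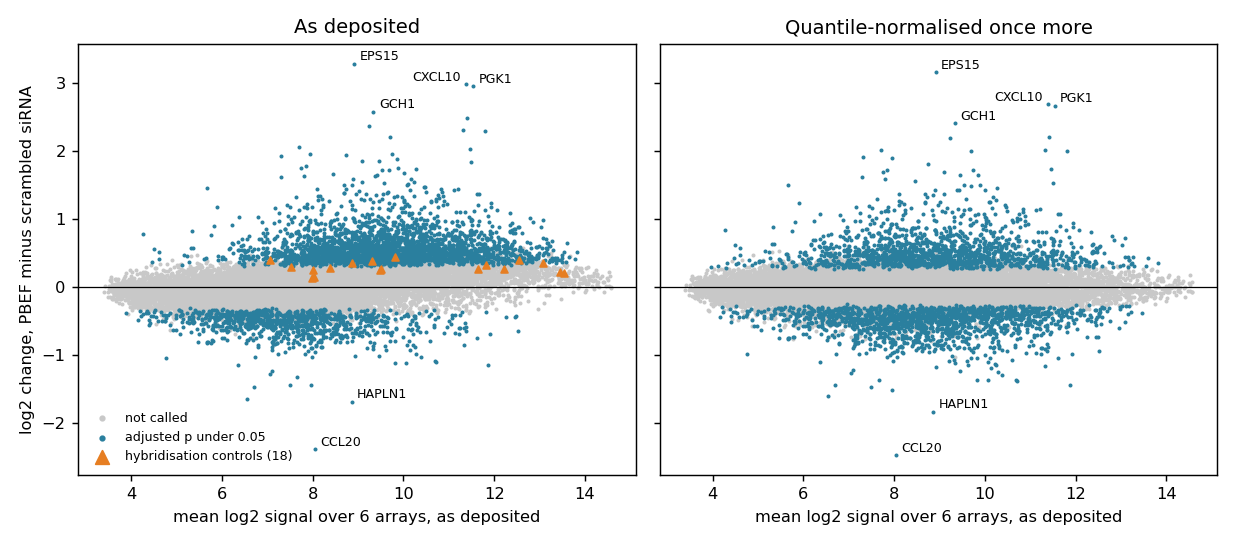
Log2 change of each gene (vertical axis, PBEF siRNA minus scrambled siRNA) against its mean log2 signal over 6 arrays (horizontal axis), for the deposited values on the left and after a further quantile normalisation on the right. Calls among bright genes are mostly higher on the left, where all 18 hybridisation controls also lie above 0, and are balanced on the right.

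Genes that interferons induce rose together. Of 39 interferon-stimulated genes measured, 31 rose, 0 fell and 8 were not called, and 38 were higher when adjusted over the list alone. Their median log2 change was 0.60 on the deposited scale and 0.35 after quantile normalisation, where 21 were higher and 0 lower. Besides CXCL10, the chemokine CXCL11 rose 4.08-fold (2.03 ± 0.16), the ubiquitin-like ligase HERC5 2.46-fold (1.30 ± 0.11) and the antiviral effector IFIT2 2.19-fold (1.13 ± 0.11). The list was called higher by camera with an adjusted p of 2.95e-18 and, after quantile normalisation, 4.04e-13. This call was not kept with the correlation between genes estimated from the data, adjusted p = 0.678 with an estimated correlation. The list's median lay above those of all 10000 random gene lists of the same size and signal level. Over the same arrays, 0 of 17 leukocyte markers rose.

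**Figure D3:**
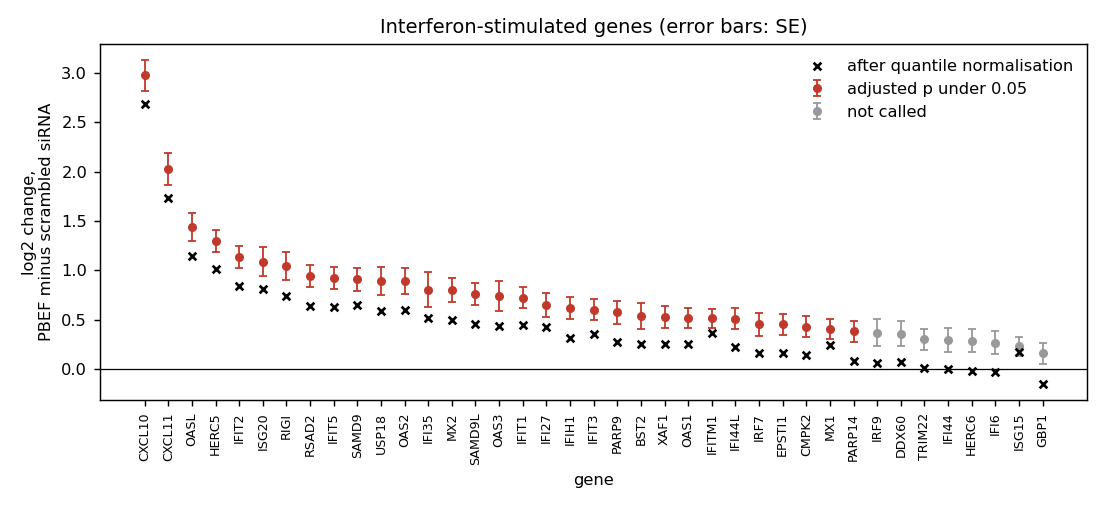
Log2 change ± SE (vertical axis, PBEF siRNA minus scrambled siRNA, n = 3 arrays per group) of the 39 measured interferon-stimulated genes (horizontal axis), with red points for called genes, grey for those not called and crosses for the change after quantile normalisation. CXCL10 and CXCL11 lead, and 31 of the genes were called higher.

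Markers of the endothelial cell itself were called higher as a list by camera with the preset correlation. They were not called with an estimated correlation (adjusted p 0.797) or by fry (adjusted p 0.134). Camera kept the call in 11 of 13 alternatives with a preset correlation. Of 25 measured, 12 rose, 0 fell and 13 were not called, with 20 higher and 2 lower when adjusted over the list alone, and the median change was 0.46. After quantile normalisation 7 were higher and 1 lower, with a median change of 0.19. The mean level of these markers was lowest on the scrambled siRNA replicate 1 array, the one with the widest ACTB gap, at 10.57 against 10.95 and 11.02 on the other scrambled siRNA arrays. The transcription factor TAL1 rose by 0.86 ± 0.12 on the log2 scale, the surface protein CLEC14A by 0.84 ± 0.13, the sialomucin EMCN by 0.64 ± 0.11 and the nitric oxide synthase NOS3 by 0.90 ± 0.17. For TAL1 and NOS3, probe sets without a cross-hybridisation suffix gave -0.047 and -0.022. By camera the adjusted p was 0.000127, with adjusted p = 0.797 with an estimated correlation, and 0.0194 after quantile normalisation. Markers of fibroblasts, mural cells, leukocytes and epithelium did not rise, and the brightest probe sets without a cross-hybridisation suffix gave no call for RGS5, MYH11, PTPRC and ELF3, although 4 of the 6 RGS5 probe sets were called lower. Of 21 fibroblast and mural cell markers, 0 rose, 3 fell and 18 were not called, with 0 higher and 2 lower when adjusted over the list alone. FAP, RGS5 and MYH11 changed by -0.75, -0.42 and -0.35, and the list was called lower, camera adjusted p 0.0131, adjusted p = 0.678 with an estimated correlation, 0.0601 after quantile normalisation, where 0 were higher and 5 lower. Of 17 leukocyte markers, 0 rose, 2 fell (CD2, -0.58, and PTPRC, -0.34) and 15 were not called, with the same 2 counts when adjusted over the list alone. That list was called lower, camera adjusted p 0.0252, adjusted p = 0.678 with an estimated correlation, 0.251 after quantile normalisation, where 0 were higher and 2 lower. Of 19 epithelial markers 0 rose, 1 fell (ELF3, -0.43) and 18 were not called, with 0 in either direction when adjusted over the list alone. Their median was -0.058 and their mean 0.00046, and camera gave an adjusted p of 0.288. On the quantile scale 1 was higher and 2 lower. Of 13 lymphatic endothelial markers 5 rose, among them NRP2 (0.65) and PDPN (0.61), 1 fell and 7 were not called, with 6 higher and 2 lower when adjusted over the list alone, camera adjusted p 0.228. On the quantile scale 2 of the lymphatic markers were higher and 2 lower, with a median of 0.054 in place of 0.31.

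Some p53 target genes and some genes of DNA synthesis also rose, while most members of both lists were not called. Of 28 p53 target genes 11 rose, 1 fell and 16 were not called, with 13 higher and 1 lower when adjusted over the list alone. The death receptor TNFRSF10B rose 3.56-fold, the damage sensor DDB2 2.10-fold, the ribonucleotide reductase subunit RRM2B 2.02-fold and GADD45A 1.66-fold. This list had a camera adjusted p of 0.000763, adjusted p = 0.797 with an estimated correlation, and 0.201 after quantile normalisation, where 6 were higher and 1 lower. Of 48 DNA replication and S-phase genes 14 rose, 1 fell and 33 were not called, with 17 higher and 3 lower when adjusted over the list alone. The helicase subunit GINS1 and the ubiquitin ligase component DTL rose 3.08-fold and 2.25-fold, and MCM3 and ORC6, which take part in helicase loading, rose 1.71-fold and 1.57-fold. Camera called the list higher with an adjusted p of 0.00604, adjusted p = 0.797 with an estimated correlation, and 0.00391 after quantile normalisation, where 9 were higher and 2 lower. The 46 genes of G2 and mitosis had no common direction, with 5 higher, 6 lower and 35 not called, and 6 in each direction when adjusted over the list alone. Their median was 0.025 and their mean 0.0089 while camera pointed lower, adjusted p 0.313. TOP2A and CKS1B rose by 0.77 and 0.83. On the quantile scale 4 of the list were higher and 6 lower, with a median of -0.061.

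Among genes of NAD and energy metabolism, the NAD consumption list was called higher by camera, adjusted p 0.0184. That call was not kept after quantile normalisation (0.298) or with an estimated correlation (adjusted p = 0.797). The NAD synthesis list was not called, and the difference between these lists was not tested. Of 25 genes in the NAD consumption list 8 rose, 1 fell and 16 were not called, with 10 higher and 2 lower when adjusted over the list alone. After quantile normalisation 4 were higher and 3 lower. The NAD hydrolase CD38 rose 2.73-fold, and the ADP-ribosyltransferases PARP12, PARP16 and PARP9 rose 1.73-fold, 1.61-fold and 1.49-fold. PARP14 rose by 0.38 on the log2 scale, and both PARP9 and PARP14 also count among the interferon-stimulated genes. The PARP9 probe set without a cross-hybridisation suffix read 0.17 and was not called. Of 20 NAD synthesis genes 4 rose, 0 fell and 16 were not called, with 4 higher and 2 lower when adjusted over the list alone. The camera adjusted p was 0.899, and 2 were higher and 0 lower after quantile normalisation. NAMPT counts here as not called, since its value in the list is that of 243296_at. By its other 3 probe sets it fell, to 11.7%, 12.1% and 23.1% of the control level. The nicotinic acid enzyme NAPRT rose 1.59-fold and the tryptophan-degrading IDO1 1.42-fold. Of 32 glycolysis and hypoxia genes 7 rose, 1 fell and 24 were not called, with 10 higher and 1 lower when adjusted over the list alone. After PGK1, the largest was HK2, 1.77-fold higher, followed in p by BNIP3 and ANKRD37 at 1.49-fold and 1.41-fold. The camera adjusted p was 0.0162, adjusted p = 0.797 with an estimated correlation, and 0.838 after quantile normalisation, where 4 were higher and 4 lower and the median was -0.016 in place of 0.22. Of 46 oxidative phosphorylation subunits 7 rose, 0 fell and 39 were not called, with 2 higher and 0 lower when adjusted over the list alone. NDUFS1 and COX8A rose by 0.50 and 0.60, and an NDUFS1 probe set without a cross-hybridisation suffix gave -0.017. The camera adjusted p was 0.000127, adjusted p = 0.797 with an estimated correlation, and 0.779 after quantile normalisation, where 0 were higher and 0 lower and the median was 0.012 in place of 0.31. The groups overlapped in the mean level of this list, which was 11.74 on PBEF siRNA replicate 3 and 11.84 on scrambled siRNA replicate 3, and lowest, 11.43, on scrambled siRNA replicate 1.

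Inflammatory, stress and sterol genes rose in part. Of 32 NF-kB targets 9 rose, 0 fell and 23 were not called, with 15 higher and 2 lower when adjusted over the list alone, and the neutrophil chemokines CXCL1, CXCL2 and CXCL8 and the adhesion molecule VCAM1 rose 1.77-fold, 1.51-fold, 1.51-fold and 1.45-fold. The camera adjusted p was 0.0162, adjusted p = 0.797 with an estimated correlation, and 0.260 after quantile normalisation, where 5 were higher and 2 lower and CXCL8 was not called. A CXCL2 probe set without a cross-hybridisation suffix read 0.13 and was not called. Of 36 genes of the unfolded protein and ATF4 responses 10 rose, 1 fell and 25 were not called, with 11 higher and 1 lower when adjusted over the list alone. DNAJB9 and XBP1 rose 1.66-fold and 1.53-fold, camera adjusted p 0.00716, adjusted p = 0.797 with an estimated correlation, 0.779 after quantile normalisation, where 3 were higher and 2 lower. The groups overlapped in this list's mean level, 10.41 on PBEF siRNA replicate 3 and 10.44 on scrambled siRNA replicate 3. Of 19 cholesterol synthesis genes 5 rose, 0 fell and 14 were not called, with 7 higher and 0 lower when adjusted over the list alone. SC5D and HMGCS1 rose 1.93-fold and 1.59-fold, camera adjusted p 0.0127, adjusted p = 0.797 with an estimated correlation, 0.408 after quantile normalisation, where 3 were higher and 1 lower. Here too the mean levels overlapped, 9.62 on PBEF siRNA replicate 3 and 9.64 on scrambled siRNA replicate 3. For SC5D, a probe set without a cross-hybridisation suffix gave -0.22. Of 27 immediate early genes 9 rose, 1 fell and 17 were not called, with 11 higher and 1 lower when adjusted over the list alone. FOSL1 and DUSP6 rose 1.96-fold and 1.70-fold, camera adjusted p 0.0463, adjusted p = 0.797 with an estimated correlation, 0.452 after quantile normalisation, where 6 were higher and 1 lower. Of 31 cytokines and chemokines 11 rose, 4 fell and 16 were not called, with 16 higher and 5 lower when adjusted over the list alone, camera adjusted p 0.0602. CXCL10 and CCL20 stood at its ends, and after quantile normalisation 9 were higher and 5 lower.

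Single genes of vessel growth, adhesion and junctions changed, and camera did not call the lists below, as deposited or after quantile normalisation. Fry did call the matrix list (adjusted p 0.0327) and the NRF2 list (adjusted p 0.0362) after quantile normalisation. Of 34 angiogenesis and Notch genes 11 rose, 2 fell and 21 were not called, with 13 higher and 5 lower when adjusted over the list alone, camera adjusted p 0.0654. The endothelial proteoglycan ESM1 rose 3.36-fold. After quantile normalisation 8 of the angiogenesis and Notch genes were higher and 5 lower, with a median of -0.035 in place of 0.20. Of 20 leukocyte adhesion molecules 7 rose, 2 fell and 11 were not called, with 8 higher and 4 lower when adjusted over the list alone, camera adjusted p 0.329. CXCL16 rose by 0.69 on the log2 scale and the integrin subunit ITGA4 changed by -0.90. On the quantile scale 5 of the adhesion molecules were higher and 4 lower, with a median of 0.020 in place of 0.14. Of 31 junction and barrier genes 7 rose, 3 fell and 21 were not called, with 8 higher and 3 lower when adjusted over the list alone, camera adjusted p 0.195. ESAM rose by 0.62 and the thrombin receptor F2R changed by -0.85, although another F2R probe set gave 0.25. After quantile normalisation 2 of these genes were higher and 5 lower. Of 39 matrix and TGF-beta targets 6 rose, 2 fell and 31 were not called, with 6 higher and 2 lower when adjusted over the list alone, camera adjusted p 0.340. ID1 and ID2 rose 2.30-fold and 1.61-fold. After quantile normalisation 3 of these genes were higher and 10 lower, with a median of -0.11 in place of 0.13. Of 32 NRF2 and antioxidant genes 6 rose, 0 fell and 26 were not called, with 6 higher and 1 lower when adjusted over the list alone, camera adjusted p 0.116. CAT and GCLC rose by 0.51 and 0.53 on the deposited scale but were not called after quantile normalisation, where 0 of these genes were higher and 3 lower, with a median of -0.085 in place of 0.19. Of 12 genes of small RNA silencing 2 rose (XPO5 among them, by 0.43, a call not kept after quantile normalisation), 1 fell (DICER1, -0.53) and 9 were not called, with the same counts when adjusted over the list alone, camera adjusted p 0.255, and 0 were higher and 1 lower after quantile normalisation. Of 42 cytosolic ribosomal proteins 0 rose, 0 fell and 42 were not called by limma, with 0 when adjusted over the list alone, camera adjusted p 0.204. RPL35 read 0.28 ± 0.12 (SE), the only one with an unadjusted p under 0.05, and RPL9 read 0.22 ± 0.12. The median of these genes was 0.11 as deposited and -0.057 after quantile normalisation.

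In all, camera called 13 of the 26 lists, 11 higher and 2 lower. After quantile normalisation it called 3, the interferon-stimulated genes, the DNA replication genes and the endothelial markers, and without the scrambled siRNA replicate 1 array, which had the widest 3' to 5' gap, it called 8. The unfolded protein, glycolysis, cholesterol synthesis, immediate early and leukocyte lists were those not called without that array. All 11 lists called higher had their lowest mean level on it. Against random lists matched in size and signal level, the medians of the unfolded protein (percentile 49.0), glycolysis (46.5), immediate early (37.1), cholesterol synthesis (73.6), oxidative phosphorylation (83.2), NAD-consuming (89.3) and p53 target (93.9) lists lay below percentile 95, and those of the NF-kB targets (95.4), the DNA replication genes (99.8) and the endothelial markers (100) above it. The fibroblast and mural list lay at 1.53 and the leukocyte list at 6.08. Camera did not call the cytosolic ribosomal proteins (percentile 0), the matrix and TGF-beta targets (0.25) or the cytokines and chemokines (99.91), although their medians were also extreme. With an estimated correlation it called 0 of 26 lists, with 0 also at an unadjusted p under 0.05, and fry, which asks only whether the genes of a list moved one way, called 1, the interferon-stimulated genes (adjusted p 0.0281), and 8 after quantile normalisation, 4 higher and 4 lower.

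**Figure D4:**
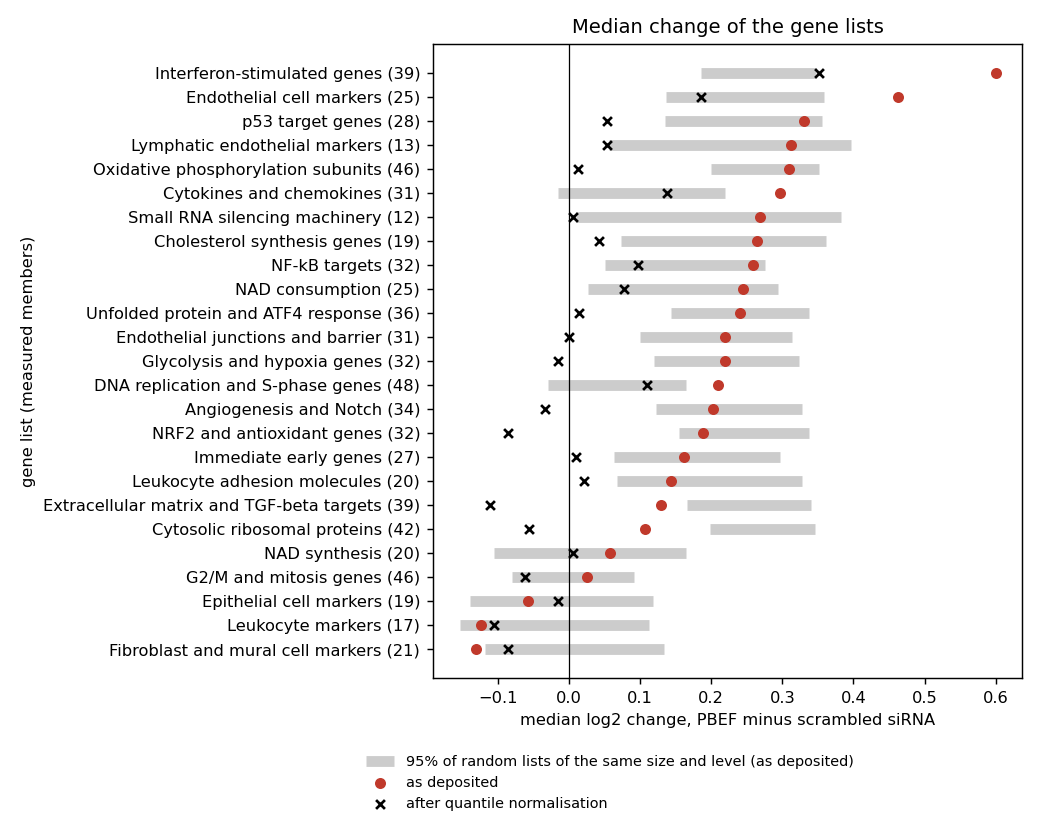
Median log2 change (horizontal axis, PBEF siRNA minus scrambled siRNA) of the gene lists (vertical axis, number of measured genes in brackets), as deposited (red points) and after quantile normalisation (crosses), with grey bars for the central 95% of random lists matched in size and signal level. On the deposited scale the interferon-stimulated genes lie farthest above their grey bar.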

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

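The correlation of the hybridisation controls with the signal range was chosen only after the result was seen, and the test of RNA quality before.

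Among probe sets left out of the gene comparison because no single gene symbol names them, 853 of 13522 were called by limma, 448 higher and 405 lower with PBEF siRNA. After quantile normalisation 323 were higher and 384 lower. The 18 hybridisation control probe sets, which should not depend on the cells, read 0.292 higher on the log2 scale on the PBEF siRNA arrays, and all 18 were higher. The exact permutation p for their mean was 0.2, where 0.1 is the smallest that 3 against 3 arrays allow, and the difference was 0.111 after quantile normalisation.

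More genes were higher than lower on the PBEF siRNA arrays, 2723 against 984. A difference in signal range between arrays is a candidate explanation, since the control probe sets rose and fell with the arrays' 95th percentile (Pearson r = 0.97, exact permutation p 0.00278; Spearman's correlation 0.94, exact permutation p 0.0167). Without the 2 arrays farthest from the median, r was 0.99, and these are 6 arrays with the groups at different levels. Inside the groups r was 1 after rounding for the PBEF siRNA arrays and 0.96 for the scrambled siRNA arrays, on few arrays each. Poor RNA on the scrambled siRNA replicate 1 array was argued against as the cause, because without that array 78.3% of 1942 called genes were still higher. The cells as the only source of the wider range are argued against by these control probe sets. They read RNA added during the assay, and they moved with the range inside each group as well. Whether the range came from the hybridisation or from the authors' processing stays open, since nothing in the labels separates these from the groups. A part played by the cells is not excluded.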

How the results depend on the processing

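Cyclic loess and both combined quantile settings were chosen only after the result was seen. Of 87 named genes that were called, 48 kept their direction and call under every alternative that gave them a value, 10 lost the call under quantile and 8 under cyclic loess normalisation. The interferon-stimulated genes were called higher by camera in all 13 alternatives with a preset correlation. With the replicate number as a block, 1794 genes were called (1448 higher, 346 lower). Deviations of same-numbered arrays from their group means correlated at -0.43, 0.16 and -0.52. Within a group such deviations sum to 0, and they also carry differences in signal range. PBEF siRNA replicate 1 had the highest 95th percentile of its group (11.34) and scrambled siRNA replicate 1 the lowest of its own (10.75). These correlations therefore cannot settle whether the numbers pair the samples. Counts of higher and lower genes were 1476 and 1597 under quantile and 1605 and 1520 under cyclic loess normalisation. Without dim genes 414 were lower. Over all probe sets, which are more features than genes, 5996 were called (4363 and 1633). With array weights 9420 were called (6191 and 3229), where the estimation of weights stopped before converging. Quantile normalisation with scrambled siRNA replicate 1 left out gave 1949 (1060 higher). Leaving out 1 array gave 1250 (without PBEF siRNA replicate 2) to 6188 genes (without PBEF siRNA replicate 3), 1067 to 4421 higher and 183 to 1767 lower. The share of calls that were higher was 80.7% with the block, 86.4% without dim genes, 79.4% with centred medians, 51.4% with cyclic loess, 65.7% with array weights, 54.4% with quantile normalisation and 1 array left out, and 71.4% to 85.4% without single arrays. Of the gene lists, 3 were called without dim genes, 1 higher and 2 lower, against 11 higher and 2 lower in the main result. After quantile normalisation 3 were called, all higher, and after cyclic loess 4. Without probe sets open to cross-hybridisation 8 were called, and 2 after quantile normalisation with scrambled siRNA replicate 1 left out. With an estimated correlation 0 lists were called, on the deposited or the quantile scale. Without single arrays there were 8 (scrambled siRNA replicate 1) to 15. The NAMPT value of 0.34 became -1.98 as the mean of its probe sets, and -2.12, -3.09 and -3.05 by the other 3. It was called at 0.38 with array weights and at 0.49 without PBEF siRNA replicate 3, and was 0.19 to 0.49 without single arrays. Without probe sets open to cross-hybridisation RGCC read -0.16, PCBP2 -0.67, RGS7 0.0053, NDUFS1 -0.017, TAL1 -0.047, NOS3 -0.022, SC5D -0.22 and F2R 0.25. Ribosomal proteins turned lower under cyclic loess (adjusted p 5.79e-05) and glycolysis genes lower under quantile normalisation with 1 array left out (0.997). The cause of these differences was not tested.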

Other observations

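The 8 gene lists below, and the tests of leukocytes, single probe sets, the glycolysis genes and the scrambled siRNA, were chosen only after the result was seen. The camera p-values of these lists were adjusted over the 8 alone. Since the lists were chosen on the same arrays, their p-values are descriptive and are not evidence of a change.

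GIMAP genes, small GTPases of the immune system also made by endothelial cells, were higher. Of 7 measured, 6 rose and 0 fell, also when adjusted over the list alone, led by GIMAP8 (1.53), GIMAP6 (1.44) and GIMAP7 (1.28). The camera adjusted p was 1.99e-06, adjusted p = 0.178 with an estimated correlation. Of 14 purine synthesis genes 6 rose and 0 fell, with 8 higher and 1 lower when adjusted over the list alone, among them PAICS (1.72), PRPS1 (1.27) and PPAT (0.95), adjusted p 0.000377, adjusted p = 0.358 with an estimated correlation. Of 31 WNT ligands and semaphorins 1 rose and 6 fell, with 1 higher and 9 lower when adjusted over the list alone, WNT5A at -0.97, adjusted p 0.000499, adjusted p = 0.172 with an estimated correlation. After quantile normalisation the adjusted p-values of these 3 lists were 8.86e-07, 0.00188 and 0.00188, with 5 GIMAP genes higher and 0 lower, 5 purine synthesis genes higher and 0 lower, and 1 WNT or semaphorin gene higher and 10 lower.

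Of 23 antigen presentation genes 10 rose and 0 fell, with 11 higher and 1 lower when adjusted over the list alone. NLRC5, the transcriptional activator of class I genes, read 0.97 and the immunoproteasome subunit PSMB9 0.86, adjusted p 0.00369, adjusted p = 0.413 with an estimated correlation. Of 18 genes in a list of RNA and DNA sensors and related genes, 9 rose and 0 fell, also when adjusted over the list alone. Among them were RIGI (1.04) and DHX58 (0.93), and the camera adjusted p was 0.00378, or 0.358 with an estimated correlation. LGALS3BP (0.75), which also rose, is no such sensor, and RIGI and IFIH1 also count among the interferon-stimulated genes. Of 21 JAK-STAT and SOCS genes 10 rose and 1 fell, also when adjusted over the list alone, adjusted p 0.00721, adjusted p = 0.382 with an estimated correlation. After quantile normalisation this list was not called (0.0820), while the antigen presentation genes and the sensors were (0.00652 and 0.0127). On that scale 5 JAK-STAT and SOCS genes were higher and 1 lower, and 7 antigen presentation genes higher and 1 lower. Of the sensor list, 4 genes were higher and 0 lower. Of 48 mitochondrial ribosomal proteins 14 rose and 0 fell, with 17 higher and 0 lower when adjusted over the list alone, adjusted p 6.24e-06, adjusted p = 0.470 with an estimated correlation, and after quantile normalisation 0.0599, with 3 higher and 1 lower and a median of 0.088 in place of 0.36. Of 26 growth factor receptors 3 rose and 3 fell, also when adjusted over the list alone, adjusted p 0.333, with EGFR at -1.14 and GHR at -0.92. On the quantile scale 1 receptor was higher and 6 lower, with a median of -0.060 in place of 0.040.

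The rise of the interferon-stimulated genes is not wholly accounted for by the wider signal range, since the list's median lay at percentile 100 of random lists matched on expression. The range may account for part of it. Those random lists had a typical median of 0.265 against 0.60, and after quantile normalisation the list's median was 0.35. The random lists do not carry the correlation between these genes. Leukocytes in the cultures are argued against by the leukocyte markers, whose median changed by -0.12. A response to the siRNA duplex and a response to the loss of NAMPT cannot be told apart. Genes of the sensor list, median 0.42, are themselves induced by interferon. The samples used here also hold no second siRNA against the target and no cells without siRNA. The interferon-stimulated genes were already bright on the scrambled siRNA arrays, whose cells also received a duplex. Their mean levels there were 11.6, 11.8 and 11.9, where the array medians were 7.02, 7.03 and 7.01. One of these responses, or an effect of the scrambled siRNA, may account for the rise, and which one is open.

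The 10 genes with the largest rise are a second open pattern. A single probe set that reads something other than its gene is argued against for EPS15, PGK1 and PKIA, whose brightest other probe sets without a cross-hybridisation suffix were called higher, by at least 1.23. For the other 7 genes it stays open, since in 0 of them the brightest such probe set was called higher. CXCL10, GCH1, PCBP1 and NCEH1 have 1 probe set. Those of ALG2, RGCC and PCBP2 read -0.087, -0.16 and -0.67, although a dimmer PCBP2 probe set without a suffix read 1.11 and was called higher. The RGCC probe set was itself dim, at 5.05 with scrambled siRNA, and another RGCC probe set with a suffix read 1.22. A rise of all glycolysis genes does not account for PGK1 (2.95), since the median of the other 31 listed genes was 0.21, with HK2 the highest at 0.82. The scrambled siRNA may instead have silenced some of these genes, which would look the same as a rise with PBEF siRNA. At 2-fold or more, 106 called genes were higher and 38 lower after quantile normalisation, which leaves this open without an untreated group.

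Of the 10 splits of the 6 arrays into 3 and 3, only the real one reached its count of 3707 genes (1 of 10), and the highest other split called 0. For the gene lists, 4 of 10 splits reached the 13 of the real one, and the highest other split called 19. After quantile normalisation 6 of 10 splits reached the 3 of the real one, and the highest other split called 5. For genes on that scale the real split called 3073 and the highest other 0. With 10 splits no share under 0.05 can be reached. Of the 13 called lists, 8 had an adjusted p as small in another split, such as 0.000101 against 0.000127 for the endothelial markers and 3.98e-11 against 0.000127 for oxidative phosphorylation. After quantile normalisation 2 of the 3 called lists did, the endothelial markers (0.00119 against 0.0194) and the DNA replication genes (0.00214 against 0.00391). For the interferon-stimulated genes, the lowest adjusted p of the other splits was 9.38e-11 against 2.95e-18, and 1.90e-07 against 4.04e-13 after quantile normalisation.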
